A study of Homo sapiens with 6 samples.

How the data were processed

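RNA was extracted with TRIzol from A549 cells after 24 h in 20 mM lactic acid or in phosphate-buffered saline (PBS), per the labels' protocols. Poly(A) RNA was captured on oligo(dT) beads, libraries were made with a Hieff NGS Ultima kit, and paired-end reads of 150 bp were taken on a NovaSeq X Plus. There were 6 libraries, 3 for each of the 2 groups, and the labels call them biological replicates.

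The authors deposited a table of whole-number counts per gene and a table of FPKM per gene for the same 6 libraries. HISAT2, StringTie and DESeq2 and the build GRCh38 are named, per the submitters' processing notes, with no version or role; the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts between near-identical copies, overlapping genes and antisense partners are therefore uncertain. The labels call the control columns WT, while the deposited tables call them NS; the columns were matched through the library names in the labels, which carry NS. The tables list 23827 genes, of which 3853 are unnamed loci (NewGene) and 19974 carry Ensembl identifiers. All of these identifiers matched GENCODE release 29 (GRCh38), which gave symbols, gene types and coordinates, and 12 symbols that a spreadsheet had turned into dates were restored through the identifiers. The gene length implied by a library's deposited count and FPKM stayed within 5% of the gene's mean over libraries for 91.8% of values in 6126 genes with at least 1000 counts.

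Totals ran from 33492831 to 42938870 counts in genes, with 17744 to 18604 genes counted at least once. Mitochondrially encoded genes took 8.88% to 10.6% of counts, unnamed loci 1.17% to 1.25%, and the 10 highest genes 9.95% to 11.4%. Replicates of a group differed by more than counting noise, with a chi-square of 6.27 to 9.11 per degree of freedom, so none was counted as a repeat of another.

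The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, two-sided, with group as the only term. TMM factors lay between 0.988 and 1.02. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15474 genes, 13717 with Ensembl identifiers and 1757 unnamed. P-values were adjusted by the Benjamini-Hochberg method over those genes, and an adjusted p under 0.05 was a call. CPM are counts scaled to an effective library of 1000000 after TMM, given as mean ± SD over 3 libraries. The SE of a log2 fold change is its size divided by the square root of F.

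Before the data were examined, 42 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 38 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the lists. Adjusted p-values of lists are from camera, and those of genes from edgeR unless another scale or tool is named. The rule named CHAC1, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, groups that did not overlap, and a proper gene symbol. It also named up to 4 members per list with the smallest p at a mean of at least 1 CPM, or up to 2 in each direction, together with ACTB, GAPDH and all members where 5 or fewer were counted. Genes named otherwise are said to have been chosen after their values were seen, and some genes that met the rule are not reported here.

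The test was checked on simulated counts for lactic acid against PBS, drawn from the means and library sizes of these samples, with 50 genes changed at each size among 15300 tested. edgeR called 48% of genes changed 1.25-fold, 88% at 1.5-fold, 92% at 2-fold and 100% at 3-fold. Of its calls, 10.4% were unchanged genes, above the nominal share, and an unadjusted p under 0.05 was found for 5.05% of 15075 unchanged genes. Far fewer genes changed in the simulation than were called in the real data. The genes changed at each size were drawn only from those above an expression floor. The shares found and the share of unchanged genes among the calls depend on this and may not carry over to the real test. Camera found the shifted simulated list (adjusted p = 8.59e-28, and 0.00723 with an estimated correlation) and called 0 of 30 unchanged lists at either setting. The simulated genes were drawn independently of each other. The check therefore could not show false list calls that come from correlated genes.

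Alternatives were median-ratio (RLE) factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 50 counts in 3 libraries, each library left out in turn, the replicate number as a block, protein-coding genes only, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with an FPKM of at least 1 in 3 libraries, or with no filter. Leaving out the unnamed loci and summing the counts of overlapping genes were chosen after seeing the data. DESeq2 was not run for gene lists. A list of nuclear-retained RNAs had 0 of its 7 members in the deposited tables and was not analysed here. A further 3 lists of other cell types had 1 or 2 tested members, too few for camera.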

Results

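Polyadenylated RNA was sequenced from A549 cells, an established line derived from a human lung adenocarcinoma, after 24 h in medium with 20 mM lactic acid or with the same volume of phosphate-buffered saline (PBS). Each group held 3 biological replicates. The title of the series names ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, and CHAC1, a glutathione-degrading enzyme. The comparison therefore asks which transcripts differed after lactic acid, with that gene and that process in view. Lactic acid brings both lactate and protons, and sodium lactate or acid alone were not analysed here. The PBS libraries held 33946788, 33492831 and 39023674 counts in genes, and the lactic acid libraries 35678633, 42938870 and 37935496. The first principal component carried 40.5% of the variance and separated the groups, with PBS libraries between −26.7 and −21.1 and lactic acid libraries between 22.8 and 25.7.

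Lactic acid changed a large share of the tested genes by small amounts. Of 15474 genes tested, 2892 rose and 2584 fell at an adjusted p under 0.05, together 35.4% of the genes, and the median change among them was 1.22-fold. A change of at least 2-fold was found for 189 genes that rose and 146 that fell, and 39 genes changed at least 4-fold. The 2-fold counts were 117 and 62 with a filter of 50 counts in 3 libraries, and 41 and 9 with limma-trend on log2(FPKM + 1). Among the 10 largest rises and 10 largest falls named by the rule at a mean of at least 5 CPM, only PTGS2 reached 4-fold. The values of the groups did not overlap for 47.5% of tested genes, against 10% by chance. With library totals in place of TMM the calls were 2528 rises and 2939 falls, and limma-trend on log2(FPKM + 1), a different unit, test and filter over 12145 genes, gave 1803 and 2533. Among 42 gene lists fixed before the data were examined, 38 had at least 5 tested members; camera called 17 of these up and 5 down, and 9 and 2 with an estimated correlation. Splits of the 6 libraries that mixed the groups also gave 11 to 16 lists at the preset correlation. These splits kept part of the treatment difference, so their counts are not a chance rate. The lists share members, and CHAC1 is in 3 of them.

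**Figure D1:**
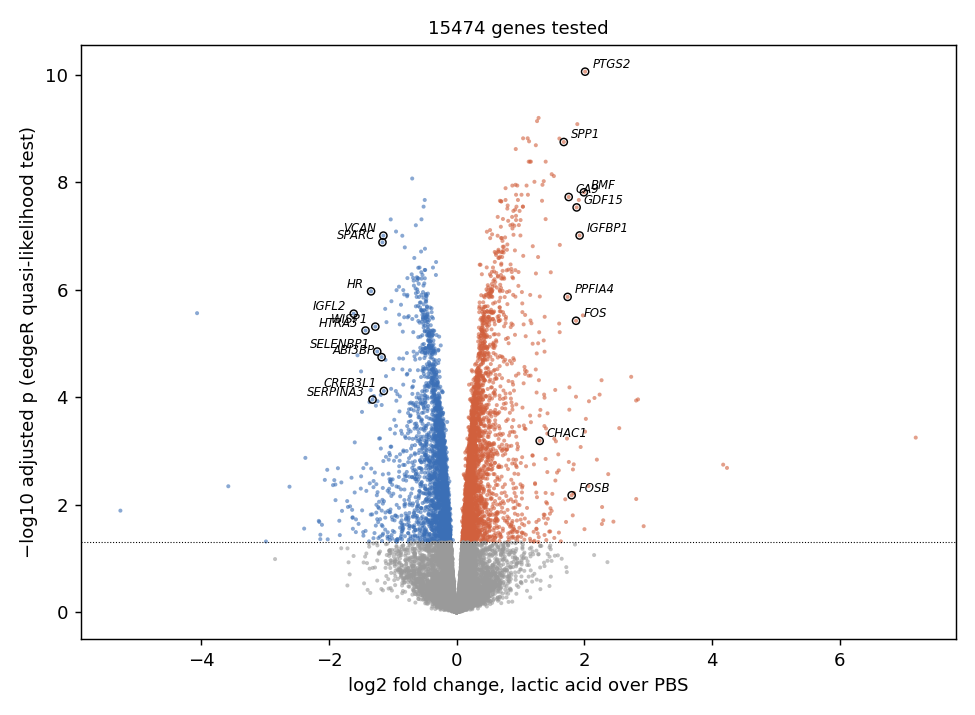
Each point is 1 of the 15474 tested genes, with the log2 fold change of lactic acid over PBS on the horizontal axis and −log10 of the adjusted p on the vertical axis, orange for genes that rose, blue for genes that fell and grey for the rest. Circles mark CHAC1 and those of the largest rises and falls at a mean of at least 5 CPM that the text names, with PTGS2 at 2.01 and IGFL2 at −1.61 as the extremes of the circled genes.

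CHAC1 transcripts rose 2.46-fold, from 0.856 ± 0.0526 to 2.11 ± 0.247 CPM (SD, n = 3 per group; log2 fold change 1.30, SE 0.215, adjusted p = 0.000648). The gene lies on chromosome 15 at 40952962 to 40956519 on the plus strand (GRCh38) and encodes an enzyme that cleaves glutathione. It was a low-abundance transcript in these cells, with 27, 30 and 35 counts in the PBS libraries and 70, 102 and 74 in the lactic acid libraries. The rise was within a wider one, since 29 of 41 tested genes of the ATF4 and integrated stress response list rose and 1 fell (29 and 2 when adjusted over the list alone; median log2 fold change 0.41). TRIB3, a pseudokinase induced by ATF4, rose 3.05-fold from 42.3 ± 2.50 to 129 ± 3.60 CPM. STC2, a secreted glycoprotein, rose 2.87-fold, GDF15, a stress-induced cytokine, 3.68-fold, and SLC38A2, a neutral amino acid transporter, 1.79-fold. SHMT2, the mitochondrial serine hydroxymethyltransferase, was the member that fell (log2 fold change −0.23, adjusted p = 0.00146; −0.18 and 0.0986 on the log2(FPKM + 1) scale). ATF4 itself, chosen after its value was seen, rose 1.35-fold, and DDIT3, chosen likewise, 1.91-fold from 3.44 ± 1.05 to 6.59 ± 0.117 CPM. Camera placed the list above other genes (adjusted p = 2.21e-19, and 0.0163 with an estimated correlation). On the log2(FPKM + 1) scale the change in CHAC1 was 0.52, and 1.03 with a pseudocount of 0.1, and both stayed past the threshold.

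Among genes that promote ferroptosis, 11 of 22 tested rose and 3 fell, the same counts as when adjusted over the list alone. POR, a cytochrome P450 reductase that feeds lipid peroxidation, rose 1.49-fold (71.1 ± 3.66 to 106 ± 4.10 CPM), and ACSL4, which activates polyunsaturated fatty acids, rose 1.32-fold (237 ± 6.56 to 312 ± 4.07). Members that fell included HMGB1, a chromatin protein released from dying cells (log2 fold change −0.22), and NOX4, a superoxide-producing oxidase (−1.54, at 0.459 ± 0.123 CPM in PBS). The list was called up by camera (median log2 fold change 0.22, adjusted p = 0.0106; adjusted p = 0.104 with an estimated correlation). The call of NOX4 was lost without the second or the third PBS or the second or the third lactic acid library (adjusted p from 0.053 to 0.104). HMGB1, which has many processed pseudogenes, stood at 0.033 in the FPKM table.

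Of the genes listed as protecting against ferroptosis, 17 of 26 tested rose and 4 fell, also when adjusted over the list alone (median log2 fold change 0.26; camera adjusted p = 2.22e-10, and 0.0380 with an estimated correlation). SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose 2.43-fold, from 1178 ± 37.5 to 2867 ± 97.4 CPM. DHCR7, the last enzyme of cholesterol synthesis, rose 2.05-fold; it stands in this list although it uses up 7-dehydrocholesterol, a sterol known to protect against ferroptosis. The members that fell were HSPB1, a small heat shock protein (log2 fold change −0.33), the membrane-bound acyltransferases MBOAT1 (−1.02) and MBOAT2 (−0.13), and DHODH, the pyrimidine-synthesis enzyme of the inner mitochondrial membrane (−0.35, adjusted p = 0.0460). Chosen after their values were seen, SLC7A11, the cystine importer, rose 1.16-fold and GPX4, the lipid hydroperoxidase at the centre of the process, rose 1.10-fold (adjusted p = 0.0231). The DHODH call was lost without any 1 of the PBS libraries or without the third lactic acid library (adjusted p from 0.0531 to 0.146), and on the log2(FPKM + 1) scale, where the log2 fold change was −0.14 (0.235). That of GPX4 was lost without the first or the third PBS or the second or the third lactic acid library (0.0591 to 0.102), and on the log2(FPKM + 1) scale (0.0849). Glutathione genes as a list were not called (9 of 27 rose and 3 fell; 10 and 3 when adjusted over the list alone; median log2 fold change 0.015, which is −0.0068 with library totals alone; camera adjusted p = 0.209). Within it MGST1, a membrane glutathione transferase, rose 1.32-fold and GSR, glutathione reductase, 1.28-fold. GSTM3 and GSTA4, cytosolic glutathione transferases, fell with log2 fold changes of −0.69 (adjusted p = 0.06 on the log2(FPKM + 1) scale) and −0.57, and GGCT, a gamma-glutamylcyclotransferase, with −0.16.

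**Figure D2:**
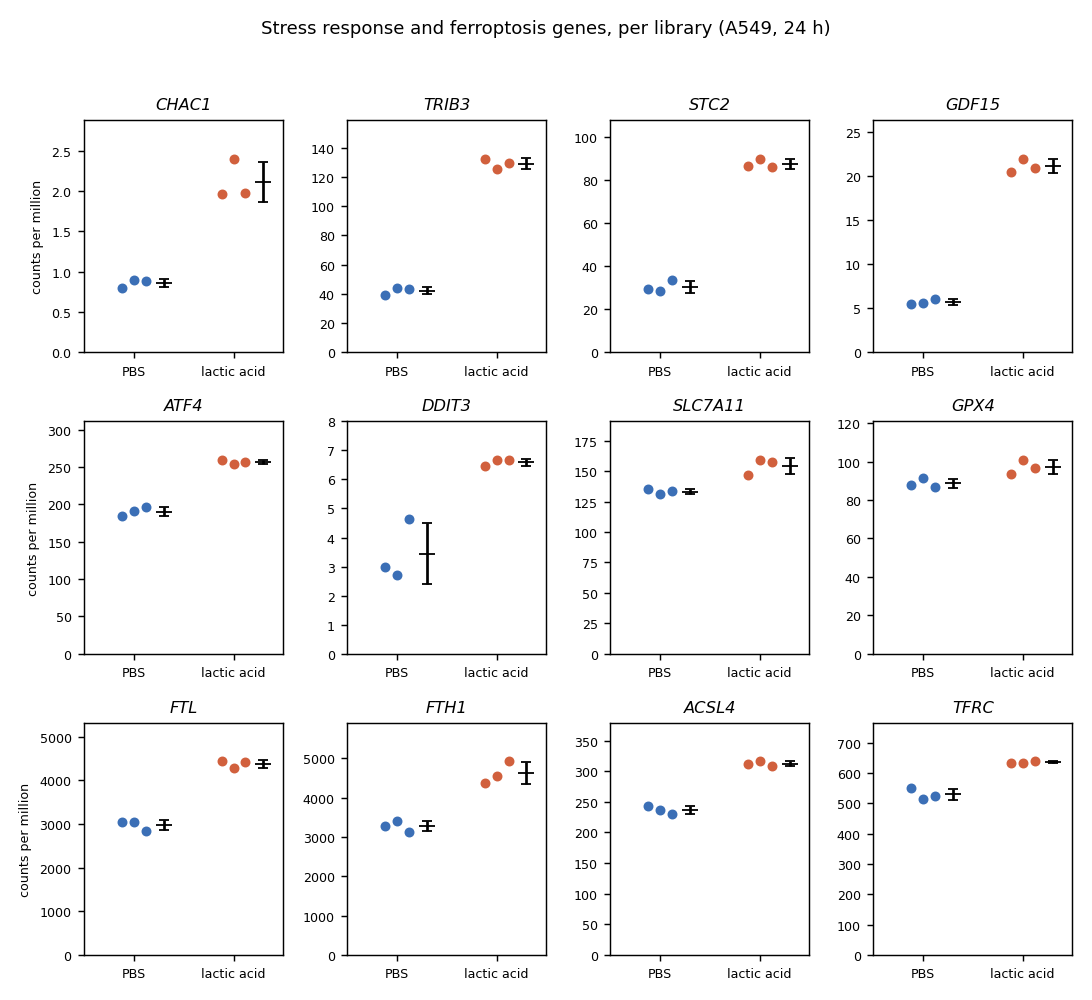
CPM values in each of the 3 PBS (blue) and 3 lactic acid (orange) libraries for 12 stress response and ferroptosis genes, with the group mean and SD in black, each vertical axis starting at 0. CHAC1 went from 0.856 to 2.11 CPM on average, and GPX4 from 88.6 to 97.0.

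Antioxidant and iron genes shifted upward in part. Of 29 tested targets of NRF2, the transcription factor of the oxidative stress response, 18 rose and 3 fell, also when adjusted over the list alone. TXNRD1, thioredoxin reductase, rose 1.44-fold and HMOX1, haem oxygenase, 1.57-fold (80.3 ± 2.22 to 126 ± 1.99 CPM), while ABCC3, a drug efflux pump, TRIM16L and CBR3, a carbonyl reductase, fell with log2 fold changes of −0.12, −0.10 and −0.40. A549 carries inactive KEAP1, so NRF2 targets are high in this line to begin with. For iron handling, 13 of 21 rose and 3 fell, also when adjusted over the list alone. FTL, the ferritin light chain, rose 1.47-fold from 2979 ± 122 to 4378 ± 86.7 CPM, and FTH1, the heavy chain, 1.41-fold; both have processed pseudogenes that can take or lend reads. FBXL5, the iron-sensing ligase subunit, STEAP2, a metalloreductase, and SLC25A28, a mitochondrial iron importer, fell with log2 fold changes of −0.32, −0.35 and −0.33. Camera called the NRF2 list (adjusted p = 1.46e-07; adjusted p = 0.169 with an estimated correlation) and the iron list (adjusted p = 0.000492; adjusted p = 0.272 with an estimated correlation). The call of TRIM16L was lost without the second PBS library or any 1 of the lactic acid libraries (adjusted p from 0.0535 to 0.0913), and that of CBR3 without any 1 of the 6 libraries (0.0629 to 0.121).

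Cholesterol synthesis and uptake genes rose almost without exception. Of 24 tested, 23 rose and 0 fell, also when adjusted over the list alone, with a median change of 1.73-fold; PMVK, phosphomevalonate kinase, was the remaining gene (log2 fold change 0.056, adjusted p = 0.585). INSIG1, the sterol-sensing protein of the endoplasmic reticulum, rose 2.39-fold from 129 ± 0.536 to 310 ± 2.35 CPM. IDI1, HMGCS1 and MSMO1, enzymes of the mevalonate and sterol pathway, rose 2.20-fold, 2.22-fold and 2.24-fold. Fatty acid synthesis and desaturation followed, with 13 of 18 genes up and 1 down, also when adjusted over the list alone, a median log2 fold change of 0.38. FADS2, a desaturase, rose 1.70-fold, and GPAM, which starts glycerolipid synthesis, fell with a log2 fold change of −0.36. Camera gave adjusted p = 5.08e-80 for the sterol list and 3.83e-19 for the fatty acid list, and 0.0159 and 0.0226 with an estimated correlation.

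Glucose use and hypoxia-inducible genes rose in the same cells. In the glycolysis list 18 of 20 genes rose and 0 fell, also when adjusted over the list alone (median 1.41-fold), and in the hypoxia-inducible list 24 of 26 rose and 0 fell (25 and 0 when adjusted over the list alone; median 1.60-fold). SLC2A3, a high-affinity glucose transporter, rose 2.63-fold (27.0 ± 1.73 to 71.0 ± 0.689 CPM), PGK1, phosphoglycerate kinase, 1.62-fold, ENO2, an enolase, 1.74-fold and ALDOA, an aldolase, 1.44-fold. CA9, a cell-surface carbonic anhydrase, rose 3.38-fold (10.2 ± 0.852 to 34.5 ± 1.28), NDRG1, a hypoxia-induced growth suppressor, 2.14-fold and VEGFA, the angiogenic growth factor, 2.00-fold. Camera gave adjusted p = 1.11e-29 for glycolysis and 5.89e-43 for hypoxia, and 0.0226 and 0.0159 with an estimated correlation. GAPDH, often used as a reference, rose 1.28-fold, and ACTB fell (log2 fold change −0.28), under every scaling tried.

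Genes that move protons rose as well. In the pH regulation list 13 of 18 genes rose and 3 fell, also when adjusted over the list alone (median log2 fold change 0.29; camera adjusted p = 9.01e-07, and 0.0244 with an estimated correlation). CA12, another cell-surface carbonic anhydrase, rose 1.64-fold from 186 ± 8.47 to 306 ± 3.33 CPM. The bicarbonate carriers SLC4A7 and SLC4A8 and the proton-gated channel ASIC1 fell, with log2 fold changes of −0.25, −0.31 and −0.40. Of 12 tested genes for lactate and pyruvate transport, interconversion and sensing, 3 rose and 1 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.125). LDHA, lactate dehydrogenase A, rose 1.56-fold (1956 ± 92.3 to 3052 ± 88.1), SLC16A3, the lactate exporter MCT4, 1.32-fold, MPC1, a subunit of the mitochondrial pyruvate carrier, 1.33-fold (adjusted p = 0.0426), and EMB, a chaperone of lactate transporters, fell with a log2 fold change of −0.20. The MPC1 call was lost in each fit with a library left out except that without the first lactic acid library, with adjusted p between 0.0653 and 0.149 in the others, and that of SLC4A8 without the second or the third PBS or the first or second lactic acid library (0.0513 to 0.106).

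TXNIP, a suppressor of glucose uptake, showed a fall of 16.7-fold, from 2.37 ± 0.502 to 0.139 ± 0.0310 CPM (log2 fold change −4.06, SE 0.324, adjusted p = 2.73e-06). Its level after lactic acid was near the floor, and on the log2(FPKM + 1) scale with no filter the change was −0.76, still past the threshold. The list it belongs to, targets of the glucose-sensing factor MondoA, was not called (2 rose and 2 fell of 8; 3 and 4 when adjusted over the list alone; camera adjusted p = 0.927). ARRDC3, an arrestin relative of TXNIP, rose 1.60-fold, FBXO32, a ubiquitin ligase subunit, rose 1.38-fold, and KLF10, a zinc finger factor, fell with a log2 fold change of −0.24. For the tricarboxylic acid cycle and pyruvate entry 5 of 26 genes rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.290). Over the alternatives the rises in this list ran from 3 to 6 and the falls from 0 to 7. PDP1 and PDK1, the phosphatase and kinase that switch pyruvate dehydrogenase on and off, rose 1.95-fold and 1.88-fold, the cycle enzyme IDH3G 1.12-fold, and PDK3, another such kinase, 1.23-fold. PDK2, of the same kinase family, and SUCLG1, a succinyl-CoA ligase subunit, fell with log2 fold changes of −0.21 and −0.13. The PDK2 call was lost without the first or the third PBS or the first lactic acid library (adjusted p from 0.0543 to 0.067), and that of SUCLG1 without the first PBS or the first or the third lactic acid library (0.0601 to 0.0716). The IDH3G call was lost without the second or the third PBS or the second or the third lactic acid library (0.0542 to 0.0814), and that of PDK3 without the third PBS library (0.0589) and on the log2(FPKM + 1) scale (0.0576). In fatty acid oxidation 1 of 20 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.271). ETFB and ACADVL, of mitochondrial electron transfer and long-chain oxidation, fell with log2 fold changes of −0.38 and −0.22. Nuclear-encoded respiratory chain subunits numbered 9 rises and 2 falls among 31, also when adjusted over the list alone (camera adjusted p = 0.568), among them COX6C at 1.25-fold, NDUFA4 at 1.22-fold, CYC1 at −0.21 on the log2 scale and NDUFV1 at −0.24. The 9 rises became 4 or 5 without the second or the third PBS or the first or the second lactic acid library.

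Lysosomal and autophagy genes rose in 20 of 25 cases and fell in 1 (21 and 1 when adjusted over the list alone), with a median of 1.25-fold. SQSTM1, the autophagy receptor p62, rose 2.06-fold from 335 ± 8.70 to 689 ± 3.16 CPM. NEU1, a lysosomal sialidase, rose 2.54-fold, FLCN, folliculin, 2.06-fold and GABARAPL1, an autophagosome protein, 1.57-fold. TFEB, a master regulator of lysosome genes, had a log2 fold change of −0.35 (adjusted p = 0.0352), a call lost in 5 of the 6 fits with a library left out, all but that without the first PBS library (adjusted p from 0.0536 to 0.115). Camera gave adjusted p = 1.01e-20, and 0.0159 with an estimated correlation.

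**Figure D3:**
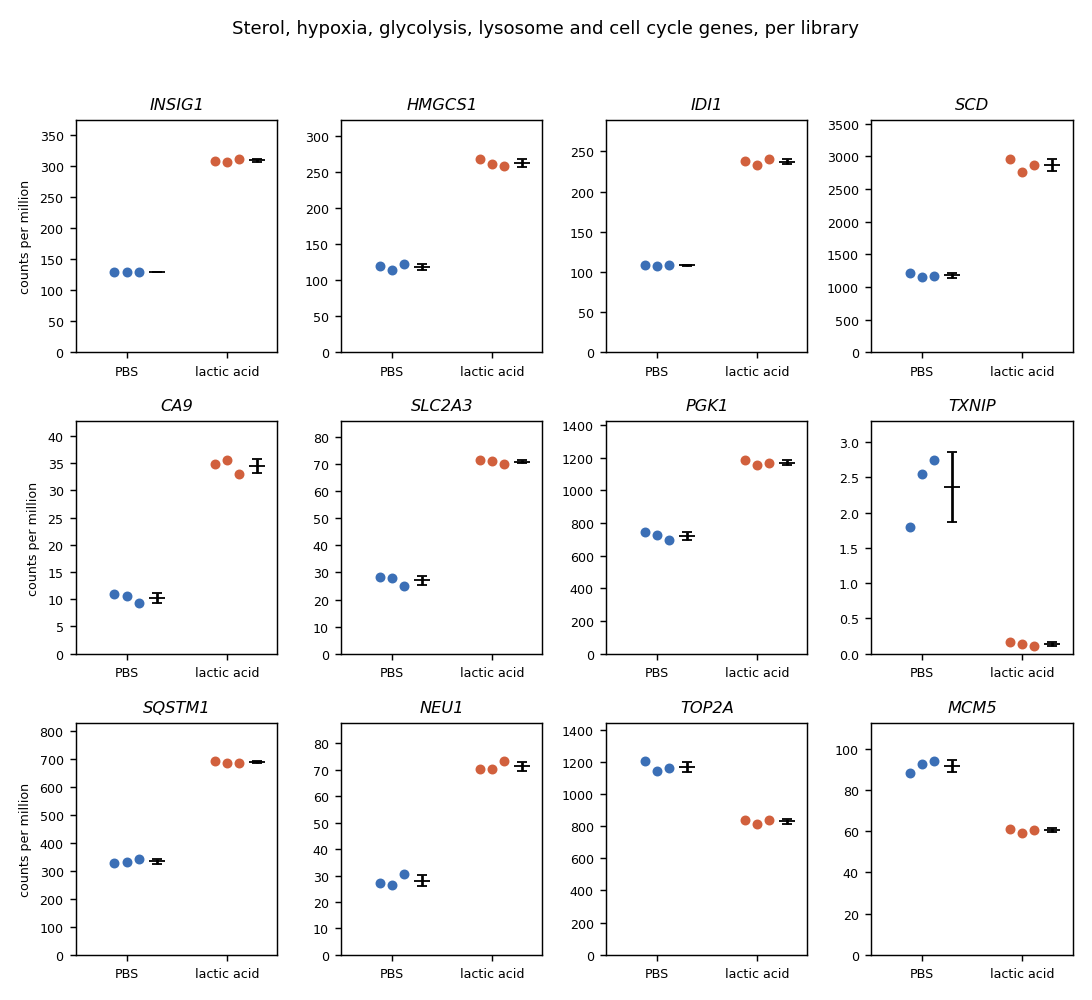
CPM values in each of the 3 PBS (blue) and 3 lactic acid (orange) libraries for 12 genes of sterol and fatty acid synthesis, hypoxia, glycolysis, lysosomes and the cell cycle, with the group mean and SD in black, each vertical axis starting at 0. The groups do not overlap for any gene shown, from SCD at 1178 and 2867 CPM to TXNIP at 2.37 and 0.139.

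Proliferation genes fell. All 26 tested genes of G2 and mitosis fell and 0 rose, also when adjusted over the list alone, with a median log2 fold change of −0.49. TOP2A, topoisomerase II alpha, went from 1170 ± 30.1 to 829 ± 13.4 CPM (−0.50), CCNB1, cyclin B1, from 208 ± 5.0 to 144 ± 0.720 (−0.53), HMMR, a spindle-associated receptor, changed by −0.60 and CDC20, an activator of the anaphase-promoting complex, by −0.67. In the S phase list 24 of 26 genes fell and 0 rose, also when adjusted over the list alone, with a median of −0.39. MCM5, MCM7, MCM10 and MCM3, replication factors, had log2 fold changes of −0.60, −0.50, −0.62 and −0.61, and the remaining genes were RRM2 (0.050, adjusted p = 0.341) and CCNE2 (0.21, adjusted p = 0.20; 0.34 and 0.0224 without the first lactic acid library). Camera gave adjusted p = 1.75e-38 for G2 and mitosis and 6.99e-19 for S phase, and 0.0220 and 0.0342 with an estimated correlation. Replication-dependent histone transcripts, fixed as a technical list because most lack a poly(A) tail, rose in 7 of 10 cases and fell in 0 (8 and 0 when adjusted over the list alone; camera adjusted p = 1.26e-05; adjusted p = 0.104 with an estimated correlation). HIST1H2AC rose 1.73-fold, HIST1H2BK 1.84-fold, HIST2H2BE 1.90-fold and HIST1H2BD 1.61-fold; near-identical copies make single histone counts uncertain.

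In the p53 target list 13 of 25 genes rose and 2 fell, also when adjusted over the list alone, and in the apoptosis list 10 of 23 rose and 0 fell (11 and 0 when adjusted over the list alone). Over the alternatives the p53 rises ran from 8 to 13 and the falls from 1 to 2, and the apoptosis rises ran from 6 to 11. TP53INP1, an autophagy and stress protein, rose 1.98-fold and CDKN1A, the cell cycle inhibitor p21, 1.41-fold from 151 ± 6.24 to 213 ± 4.42 CPM, while TP53I11 and TP53I3 had log2 fold changes of −0.18 and −0.13. The TP53I3 call was lost in every fit with a library left out except that without the first PBS library (adjusted p from 0.0534 to 0.122). BMF, a pro-apoptotic BH3-only protein, rose 3.98-fold (7.19 ± 0.180 to 28.6 ± 2.17), and BCL2L11, the related protein BIM, 1.33-fold; BIRC3, an inhibitor of apoptosis, rose 1.43-fold. Camera called the p53 target list (adjusted p = 2.06e-05, and adjusted p = 0.103 with an estimated correlation). It also called the apoptosis list (adjusted p = 0.00164, and adjusted p = 0.0653 with an estimated correlation). The apoptosis median log2 fold change of 0.107 lay within −0.101 to 0.115, the central range of random lists matched on expression. That of p53 targets, 0.150, lay above its range of −0.0817 to 0.105.

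Protein folding genes were split. Of 19 cytosolic heat shock genes 10 fell and 0 rose (12 and 1 when adjusted over the list alone; median log2 fold change −0.14; camera adjusted p = 0.000112; adjusted p = 0.252 with an estimated correlation). FKBP4, a co-chaperone of HSP90, fell with a log2 fold change of −0.46 and HSP90AA1, the inducible HSP90, with −0.27, from 2163 ± 49.6 to 1789 ± 37.8 CPM; HSPA1A stood at −0.49, but its count is uncertain because HSPA1B is nearly identical. Among 21 genes for chaperones and degradation in the endoplasmic reticulum 8 rose and 7 fell (9 and 7 when adjusted over the list alone; camera adjusted p = 0.290). EDEM1, which sends misfolded glycoproteins to degradation, and HERPUD1, of the same pathway, rose 1.34-fold and 1.33-fold. CALR and HSP90B1, abundant chaperones of that compartment, fell with log2 fold changes of −0.17 each.

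In the NF-kappaB and cytokine list 15 of 25 genes rose and 0 fell (16 and 1 when adjusted over the list alone; median 1.28-fold; camera adjusted p = 7.57e-14, and 0.0342 with an estimated correlation). PTGS2, cyclooxygenase-2, rose 4.03-fold from 29.1 ± 0.431 to 117 ± 3.28 CPM, SOD2, the mitochondrial superoxide dismutase, 2.16-fold, and CCL2, a monocyte chemokine, 1.49-fold. Of 24 interferon-stimulated genes 13 rose and 3 fell (14 and 3 when adjusted over the list alone; camera adjusted p = 0.00164; adjusted p = 0.272 with an estimated correlation). IFI6 rose 1.61-fold and DDX58, the RNA sensor RIG-I, 1.41-fold, while IFI44, GBP1 and OASL fell with log2 fold changes of −0.58, −0.25 and −0.58. The OASL call was lost without the first or second PBS or the first or the third lactic acid library (adjusted p from 0.0679 to 0.0937). Immediate early genes numbered 9 rises and 4 falls among 20, also when adjusted over the list alone (camera adjusted p = 0.00541; adjusted p = 0.305 with an estimated correlation). KLF6, a zinc finger factor, rose 1.44-fold and DUSP5, a phosphatase of ERK, 1.71-fold; MYC, JUNB, FOSL1 and EGR2, transcription factors of the same class, fell with −0.27, −0.29, −0.36 and −2.62. The FOSL1 call was lost without any 1 of the 6 libraries but the first PBS library (adjusted p from 0.0513 to 0.208), and on the log2(FPKM + 1) scale (0.111). EGR2 was near the floor, at 0.805 ± 0.172 CPM in PBS and 0.124 ± 0.110 in lactic acid with 0 in the first lactic acid library, and its log2 fold change was −2.09 without the first and −3.25 without the second lactic acid library. Antigen presentation and checkpoint genes were not called as a list (6 rose and 3 fell of 18, also when adjusted over the list alone; camera adjusted p = 0.808). CD276, a checkpoint ligand, rose 1.23-fold and TAPBP, tapasin, 1.18-fold, while HLA-B, HLA-C and PSMB9, parts of class I presentation, fell with log2 fold changes of −0.59, −0.17 and −0.51. The PSMB9 call was lost without any 1 of the libraries but the second lactic acid library (adjusted p from 0.0622 to 0.125).

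Adhesion and matrix genes changed in both directions. In the mesenchymal and invasion list 5 of 24 rose and 7 fell (5 and 9 when adjusted over the list alone; median log2 fold change −0.063; camera adjusted p = 0.0140; adjusted p = 0.409 with an estimated correlation, and 0.0812 with limma-voom). TGFBI, a matrix adhesion protein, fell from 5616 ± 151 to 3973 ± 13.7 CPM (−0.50), and SPARC, a collagen-binding glycoprotein, from 77.8 ± 5.91 to 34.7 ± 2.52 (−1.16); ITGB3, an integrin subunit, rose 1.35-fold and PLAUR, the urokinase receptor, 1.16-fold. The other rises were those of LOXL2, a collagen cross-linking enzyme (1.10-fold), CDH2, N-cadherin (1.08-fold), and MMP1, a collagenase (log2 fold change 1.70, at 0.211 ± 0.0576 to 0.696 ± 0.238 CPM). The CDH2 call was lost without the third PBS or the third lactic acid library (adjusted p = 0.0527 and 0.051) and on the log2(FPKM + 1) scale (0.0877), and that of MMP1 without the second lactic acid library (0.0505). The median of the mesenchymal list lay within −0.0938 to 0.112, the central range of random lists matched on expression. Of 16 epithelial genes 4 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.422). KRT7, a simple-epithelium keratin, had a log2 fold change of −0.52 and CDH1, E-cadherin, −0.77, while ELF3, an epithelial transcription factor, rose 1.73-fold DSP, desmoplakin, 1.29-fold, MUC1, a membrane mucin, 1.59-fold (adjusted p = 0.303 on the log2(FPKM + 1) scale) and KRT19, another keratin, 1.14-fold. Of the genes used as fibroblast markers, 5 of 8 tested fell and 0 rose (6 and 0 when adjusted over the list alone; camera adjusted p = 0.00780; adjusted p = 0.104 with an estimated correlation). These were COL1A1 (−0.49), LUM (−0.69), DCN (−1.04), THY1 (−0.25) and COL3A1 (−1.20), and without the second lactic acid library the calls of DCN, THY1 and COL3A1 were lost (adjusted p = 0.0525, 0.0624 and 0.0741). The COL3A1 call was also lost without the first or second PBS library (0.0522 and 0.0783). COL3A1 was near the floor, at 1.07 ± 0.266 CPM in PBS and 0.466 ± 0.145 in lactic acid. With limma-trend on log2(FPKM + 1) and no filter its change was −0.13 (adjusted p = 0.0612). The 12 fibroblast markers summed to 149.9 ± 7.14 CPM in PBS and 109 ± 4.15 in lactic acid, of which COL1A1 alone stood at 112 and 79.7.

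Further named changes came from the genes with the largest calls at 5 or more CPM. Besides PTGS2, BMF, GDF15 and CA9, the 10 largest rises included those of IGFBP1, an insulin-like growth factor binding protein (3.80-fold), the AP-1 subunits FOS (3.65-fold, 22.5 ± 4.36 to 82.5 ± 18.0 CPM) and FOSB (3.49-fold, SE 0.430 on the log2 scale, adjusted p = 0.00666), PPFIA4, a liprin (3.34-fold), and SPP1, osteopontin (3.20-fold). The 10 largest falls were those of IGFL2 (3.06-fold lower), HTRA3, a serine protease (2.69-fold), HR, the hairless corepressor (2.53-fold), SERPINA3, a protease inhibitor (2.49-fold), WISP1, a Wnt-induced matricellular protein (2.42-fold), SELENBP1, a selenium-binding protein (2.37-fold), ABI3BP (2.26-fold), SPARC (2.24-fold), VCAN, versican (2.21-fold), and CREB3L1, a transcription factor of the secretory pathway (2.20-fold). FOSB varied widely within groups, at 5.36, 1.78 and 7.31 CPM in PBS and 20.6, 22.6 and 7.68 in lactic acid, and its adjusted p was 0.0525 on the log2(FPKM + 0.1) scale.

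**Figure D4:**
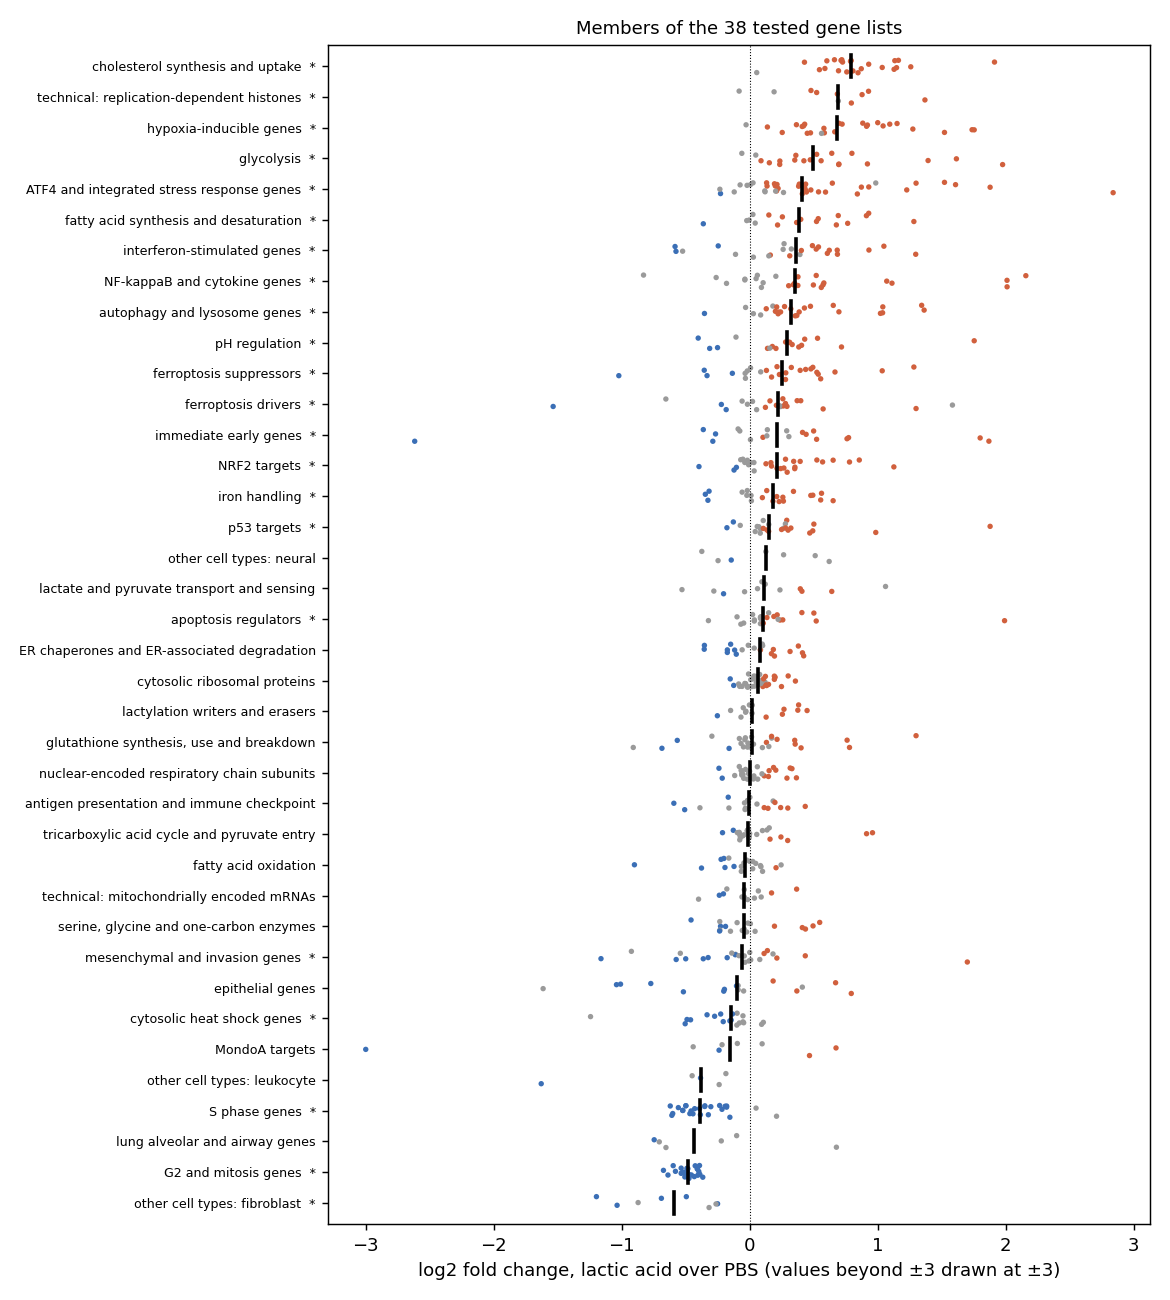
Each point is a tested member of a gene list, placed by its log2 fold change of lactic acid over PBS, orange if it rose, blue if it fell and grey if it did not pass the test; black bars mark the list medians and asterisks the 22 lists called by camera. Cholesterol genes stand at the top with a median of 0.79 and fibroblast markers at the bottom with −0.59.

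The remaining lists were not called by camera. Of 15 tested writers and erasers of lysine lactylation 6 rose and 1 fell, also when adjusted over the list alone (median log2 fold change 0.019, which is −0.0027 with library totals alone; adjusted p = 0.129), among them AARS, an alanyl-tRNA synthetase, at 1.30-fold and SIRT2, a deacylase, at 1.31-fold, against AARS2 at −0.25 on the log2 scale, a call lost without the first PBS library (adjusted p = 0.0545) or the second lactic acid library (0.0574). Serine, glycine and folate enzymes counted 5 rises and 4 falls among 19 (5 and 5 when adjusted over the list alone; adjusted p = 0.958): PSAT1 and PSPH of serine synthesis rose 1.35-fold and 1.33-fold, the serine transporter SLC1A4 1.41-fold and the folate enzyme MTHFD2 1.14-fold (adjusted p = 0.051 on the log2(FPKM + 1) scale), and TYMS, SHMT2 and MTHFD1 of folate-dependent synthesis fell with −0.46, −0.23 and −0.19. Cytosolic ribosomal protein genes counted 13 rises and 2 falls among 37 (14 and 2 when adjusted over the list alone; adjusted p = 0.237), with RPS27 up 1.28-fold, RPL8 at −0.15 and RPL13 at −0.12. The 13 rises became 5 to 8 without the second or the third PBS or the first or the second lactic acid library, 5 on the log2(FPKM + 1) scale and 0 there with no filter, but 16 without the third lactic acid library, and the RPL13 call was lost without the second PBS or the first or the third lactic acid library (adjusted p from 0.0862 to 0.107) and on the log2(FPKM + 1) scale (0.586). Mitochondrially encoded mRNAs counted 2 rises and 2 falls among 13, also when adjusted over the list alone (adjusted p = 0.803), namely MT-ND3 (0.37), MT-CO3 (0.17), MT-CYB (−0.24) and MT-ND5 (−0.20), of which MT-CO3 was lost without the second or the third PBS or the second or the third lactic acid library (adjusted p from 0.0939 to 0.197) and MT-ND5 without the first or second PBS or the first lactic acid library (0.0692 to 0.0888). Lung alveolar and airway genes counted 1 fall among 6, that of TP63 (−0.75; list adjusted p = 0.274), and neural markers 1 fall among 7, that of SNAP25 (−0.14; list adjusted p = 0.958). Leukocyte markers counted 2 falls among 5, those of CD68 (−0.38) and CD79A (−1.63; list adjusted p = 0.129), and the CD79A call was lost without the third PBS or the first or second lactic acid library (adjusted p from 0.0503 to 0.0851). Endothelial markers had 1 fall among 2 tested, that of EGFL7 (−0.36), and the hepatocyte and kidney markers and the erythroid and platelet markers had 0 calls among 2 and 1 tested, so that these were too few for a list test. The median, the mean and the direction of the camera test differed in sign for the MondoA, tricarboxylic acid cycle, respiratory chain, antigen presentation, serine and neural lists, none of them called.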

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

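All alternatives were fixed before the data were examined except leaving out the unnamed loci and summing overlapping genes, which were chosen after seeing the data. CHAC1 kept its direction and its call under every alternative run, with adjusted p from 0.000247 to 0.0057. Its log2 fold change was 1.19 to 1.35 with a library left out, 1.30 with DESeq2, and with limma-trend 1.03 on the log2(FPKM + 0.1) scale and 0.52 on the log2(FPKM + 1) scale, so that a larger pseudocount gave a smaller change. The count of changed genes was 5476, and 4545 to 4980 with a library left out, 4809 with DESeq2, 5538 with limma-voom, 5467 with library totals alone and 4336 on the log2(FPKM + 1) scale, or 3803 there with no filter. Of the 5476 genes, 4698 were also called with DESeq2, 79.3% to 84.7% with a library left out, and 3891 on the log2(FPKM + 1) scale. Leaving out the unnamed loci gave 5300 genes, and 281 at least 2-fold.

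The count of genes changed at least 2-fold was 335, and 301 to 332 with a library left out, 179 with a filter of 50 counts in 3 libraries, which removes low genes, 50 and 116 on the log2(FPKM + 1) and log2(FPKM + 0.1) scales, and 48 with log2(FPKM + 1) and no filter, fits that differ from the edgeR test in unit, test and filter at once. Camera called 22 lists, 22 or 23 with a library left out, 11 with an estimated correlation (9 up and 2 down) and 30 by fry, which does not compare a list with other genes. With limma-voom the mesenchymal list alone lost its call.

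Of 259 single genes, 3 of 4358 values under alternatives changed sign, all of HMGB1, at 0.03323 on the log2(FPKM + 1) scale, with and without a filter, and 0.03341 with log2(FPKM + 0.1) (adjusted p = 0.805 and 0.866 with and without the filter for the first, 0.805 for the last), and the cause was not tested. Besides these, calls were lost in 189 values and gained in 15, and 194 of the 243 called genes kept their call under every alternative that gave a value. Named genes whose call was lost on the log2(FPKM + 1) scale included CDH2, DHODH, FOSL1, GPX4, GSTM3, MT-CO3, MTHFD2, MUC1, PDK3, RPL13 and SHMT2 (adjusted p from 0.051 to 0.586), and those lost with DESeq2 included CBR3, MPC1, MT-CO3, MT-ND5, OASL, PSMB9, SLC4A8 and TFEB (0.0522 to 0.192). Counts of list members that rose or fell moved by over 1.5 times in 116 of 1088 values, most of them small counts. Library totals in place of TMM moved the median of all genes from 0.0024 to −0.019 and the calls from 2892 rises and 2584 falls to 2528 and 2939.

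Replicate numbers are shared between the groups. The deviations of same-numbered libraries from their group means had correlations of 0.0218, −0.0239 and 0.031, and 3 of the 6 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate number as a block (replicate block), 5482 genes changed, 323 at least 2-fold, with 5225 of the 5476 among them, CHAC1 stood at 1.295 (adjusted p = 0.00192) and 22 lists were called. Of the genes named in the text, TFEB, DHODH, MT-CO3, MPC1, CBR3 and SENP3-EIF4A1 did not pass the test in that fit (adjusted p = 0.0504, 0.0543, 0.0559, 0.0616, 0.0673 and 0.375). NR1H3 passed there as a fall (adjusted p = 0.0463) and TUBB3 as a rise (0.0151), while neither passed the main test. At this depth the simulated test, in which far fewer genes changed, found 48% of 1.25-fold changes. That share was not estimated for the real data, where an uncalled gene can still differ by that much.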

Other observations

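The gene families described here were chosen after the results of the gene lists were seen, as were the test on ARRDC4, the reading of the LXR targets by their called members, and the counts over other splits of the libraries.

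Of 15 families taken by their symbols and tested with camera and edgeR, several shared members with the lists of the report. Genes of the vacuolar ATPase, the proton pump that acidifies lysosomes, rose in 14 of 20 cases and fell in 1 (median log2 fold change 0.27; camera adjusted p = 1.07e-05, and 0.035 with an estimated correlation), with ATP6V1E1 up 1.44-fold and ATP6V0E1 1.40-fold; ATP6V1E1 and 7 others of the 20 also stand in the pH regulation list. Solute carriers, which move metabolites and ions across membranes, rose in 74 of 220 cases and fell in 18 (median 0.11; adjusted p = 0.000518, and 0.0386 with an estimated correlation). SLC17A5, the lysosomal sialic acid exporter, rose 2.53-fold from 16.4 ± 0.726 to 41.5 ± 2.19 CPM (n = 3 per group), SLC6A6, a taurine transporter, rose 1.83-fold, and SLC29A1, a nucleoside transporter, fell (−0.44). Kinesins, motors of which many serve mitosis, fell in 14 of 36 cases and rose in 1 (median −0.22; adjusted p = 2.94e-06, and 0.035 with an estimated correlation), among them KIF15 (−0.61) and KIF23 (−0.48). Genes of the minichromosome maintenance family, the replicative helicase and its relatives, fell in 8 of 9 cases and rose in 0 (median −0.50; adjusted p = 1.5e-13, and 0.035 with an estimated correlation), but 7 of the 9 also stand in the S phase list, so this largely restates that result. Tubulins and gamma-tubulin complex genes fell in 13 of 21 cases and rose in 0 (median −0.22; adjusted p = 1.07e-05; adjusted p = 0.136 with an estimated correlation), with TUBB from 1673 to 1294 CPM. The members named here, in the next paragraph and from the second hypoxia list, and the unnamed locus, were chosen after their values were seen.

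Keratins fell in 7 of 13 cases and rose in 2 (median −0.34; camera adjusted p = 1.33e-05; adjusted p = 0.131 with an estimated correlation). KRT80 fell (−0.58), and KRT81 stood at 4406 ± 165 CPM in PBS and 3009 ± 37.9 in lactic acid, a count left uncertain by its near-identical relative KRT86. Collagen chains fell in 13 of 30 cases and rose in 3 (median −0.23; adjusted p = 0.00124; adjusted p = 0.232 with an estimated correlation), and COL6A2 went from 61.5 ± 2.29 to 31.8 ± 1.75 CPM (−0.95). Laminin chains fell in 5 of 10 cases and rose in 1 without a call for the family (adjusted p = 0.0764), with LAMA3 up 1.83-fold. Families with a camera call lost under an estimated correlation were also the proteasome subunits and assembly factors (10 of 37 fell, 1 rose; adjusted p = 0.0368, and adjusted p = 0.232 with an estimated correlation), the chaperonin (6 of 8 fell, 0 rose; 0.0296, and adjusted p = 0.278), the cathepsins (4 of 12 rose, 1 fell; 0.0379, and adjusted p = 0.179) and the HIST genes (18 of 33 rose, 0 fell; 1.13e-06, and adjusted p = 0.124). Integrins (5 rose and 6 fell of 21; adjusted p = 0.871), mitochondrial ribosomal proteins (10 and 14 of 78; 0.238) and ZNF genes (75 and 27 of 435; 0.148) were not called.

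Unnamed loci (NewGene) rose in 160 cases and fell in 105, and NewGene_164 went from 24.2 ± 0.918 to 89.9 ± 5.11 CPM (log2 fold change 1.89). Of the 13717 tested genes with Ensembl identifiers, 13714 were protein-coding, so noncoding genes were hardly covered by name. Whether an unnamed locus is a known gene of another type was not tested. SENP3-EIF4A1, whose annotation overlaps SENP3 and EIF4A1, was at 7.93, 558 and 83.7 CPM in PBS and 32.9, 4.23 and 45.6 in lactic acid (−2.99, adjusted p = 0.0483), and at −0.76 without the second PBS library (adjusted p = 0.526). The sum of the 3 overlapping genes, an alternative chosen after seeing the data, lay between 1245 and 1253 CPM in PBS and between 1151 and 1205 in lactic acid. Genes listed as markers of other cell types were summed in PBS and lactic acid. The sums were 49.2 ± 2.39 and 38.3 ± 2.26 CPM for leukocytes and 26.5 ± 2.88 and 21 ± 1.74 for endothelium. For neural genes they were 387 ± 17.2 and 388.9 ± 6.98, of which TUBB3 alone stood at 205 and 224. Whether A549 cells themselves express these genes was not tested.

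Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 5476 changed genes, 335 changed at least 2-fold and 22 lists called by camera at the preset correlation, and it was the real one. The highest among the other splits were 1 gene, 1 gene and 16 lists. Each of the other splits put libraries of both groups on each side. This raised the spread within a side, which by itself lowers the count of genes. It also left part of the treatment difference between the sides, so the counts of genes and lists are not a chance rate. With 10 splits the share cannot fall under 0.05.

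Cholesterol genes rose together, with a median log2 fold change of 0.79. Removing the trend over GC content and exon length, which held 1.31% of the variance of log2 fold changes, left the median at 0.781. That lay outside −0.0906 to 0.0911, the central range of random lists matched on expression, which argues against this trend as the whole cause. The lowest median over 3 scalings was 0.769. These scalings moved the median of all genes only between 0.0024 and −0.019, so the comparison could not have removed the rise and tests no other scaling error. Low cell sterol acting through SREBP, with LXR targets falling, may be a biological source, and was tested on 5 LXR targets. Their median was −0.26, which met the fall set for this explanation before the test was run. The reading by called members was added afterwards. The members that passed the main test rose (ABCA1 0.21, SMPDL3A 0.77), while NR1H3, ABCG1 and MYLIP did not pass. NR1H3 passed as a fall in 4 of 17 alternatives (adjusted p from 0.0386 to 0.0496), so this explanation stays undecided. Acid and lactate cannot be separated here, since both came with the same treatment.

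Hypoxia-inducible and glycolytic genes rose while TXNIP was far lower. The hypoxia list kept a median of 0.663 after the trend over GC content and length was removed (random lists −0.0992 to 0.0902), which argues against that trend as the whole cause. A higher activity of hypoxia-inducible factors is a candidate explanation, and a second list of 14 such genes had a median of 0.422, with 11 that rose and 0 that fell, among them TMEM45A (2.42-fold) and CITED2 (1.95-fold). Lower activity of MondoA could account for TXNIP, and its paralog ARRDC4 under the same factor stood at −0.441 (adjusted p = 0.0633), which leaves this open, with ARRDC3 up 1.60-fold. Oxygen in the medium, cell density and protein levels were not analysed here.

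Replication-dependent histone transcripts rose while S phase genes fell. After the trend over GC content and length was removed the histone median was 0.589 (random lists −0.2 to 0.194), which argues against that trend as the whole cause. More cells at rest was tested on H1F0, a histone gene of resting cells, which should then rise, and on H2AFZ, which should fall. H2AFZ fell (−0.20, adjusted p = 0.000539), but H1F0 fell too (−0.254, adjusted p = 0.000642), against its prediction. The fall of H1F0 alone cannot decide whether more cells were at rest, as all 26 tested G2 and mitosis genes and 24 of 26 S phase genes fell. A weaker poly(A) selection in the lactic acid libraries may be a technical source, since of the 23 other HIST genes 11 rose, 0 fell and 12 did not pass (median 0.567), although polyadenylated histone transcripts would give the same values. SLBP, which binds the tail-less histone mRNA end and was chosen after its value was seen, fell (−0.18), and the histone counts themselves are uncertain between near-identical copies.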
